A study of Hordeum vulgare with 4 samples.

How the data were processed

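Messenger RNA of barley leaves was measured by sequencing in 2 wild-type and 2 transgenic samples, assigned to groups by their titles. Libraries were prepared with a SMARTER mRNA kit, per the labels' protocols. STAR, Bowtie2, RSEM and DESeq2 are named without versions per the submitters' processing notes, and their roles and settings are not given in the sources used here. The genome build is likewise not given in the sources used here. The deposited table has 1 row per assembled transcript, with a locus identifier and a class code, and most rows are tied to HORVU gene models. This layout is of the kind that Cufflinks writes, a tool that the submitters' processing notes do not name, so which program made the FPKM and p-values is open.

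The authors deposited 1 FPKM column per group, per the file headers, as whole numbers, and these columns were treated as a score, not as counts. How the 2 samples of a group were combined is not given in the sources used here. No transcript had 0 in both columns. The authors' p-value of each transcript for the 2 groups was used as deposited. The test behind it is not given in the sources used here, the values are steps of 5e-05, and 1157 transcripts hold that smallest value. The 2 transgenic samples carry different codes in their descriptions, whose meaning is not given, and whether they come from 1 transgenic line or from several is open. Nothing in the labels says that the samples of a group came from separate plants, so these p-values measure at most the spread between these samples, which can be technical. The depth of each sample is unknown, and the rounding to whole numbers limits the precision. Of all transcripts, 49.8% had values of 2 FPKM or less in both groups. The authors' deposited table also gives each transcript a word for its class. In rows above 0 in both groups, these words follow a rule of p under 0.05 and a change of over 4-fold. With values rounded to the nearest whole number, 0 rows contradict the rule. Under truncation 20 rows would contradict it. The 18638 rows with a 0 in 1 group instead carry a word for presence in a single group, whatever their p. They could not enter this check, so whether a listed 0 stands for no signal or for a value under 0.5 FPKM is open. No columns of samples outside this series were found.

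The planned test on values per sample (a fit with 2 samples against 2) could not be made on 1 value per group, so no p-value was computed here from the FPKM values. The p-values of the authors' deposited table were adjusted over all 51141 transcripts by the Benjamini-Hochberg method, and an adjusted p under 0.05 made a call. The largest unadjusted p among the calls was 0.0021. Direction came from the 2 FPKM values, and changes are on the scale of log2(FPKM + 1) where so named, which understates the change of low transcripts. No filter on low values was used. Folds were given only where both values were above 0, with bounds from a rounding error of 0.5 FPKM in each value. Genes were named by a rule written before the data were examined, which allows at most 2 gene models that rose and 2 that fell where no product is named. They had the largest changes among calls with 5 FPKM or more in the higher group and a value above 0 in both. The limit to values above 0 in both was not part of that rule. Organelle and non-coding RNA names were described after their values were seen. None of the 17670 HORVU names matched the gene table given for the organism, which is of another assembly, and 21 other names did.

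The 33 gene lists, which covered heat response, photosynthesis, hormones and markers of other leaf cell types, are patterns on product descriptions, which the table does not give. Applied to gene symbols, 32 of the patterns matched none, and these lists were not analysed here as lists. Some symbols belong to such a list by function. Of these, rbcL and the plastid ribosomal protein genes are described with the plastid transcripts. The 4 mitochondrial transcripts, among them those named rpl2_p and rps2_p, held no call and are not described further. For the list that matched and the groups of named RNA, the median log2(FPKM + 1) change was placed among 10000 random lists drawn from 20 bins of mean level. Loci on the 7 nuclear chromosomes were ordered by position, overlapping loci were merged into units because strand is not given, and calls were shuffled 10000 times within chromosomes. This comparison of neighbours and that of loci listed at 0 in 1 group were chosen after the data were examined, describe the order of loci in these data, and are no test over replicates. In the comparison of loci listed at 0 in 1 group, units entered by their FPKM, whether called or not. Positions are from the table, with 1 added to each start so that they count from 1. Lengths of 1555 of the 5804 loci with 1 transcript equal the end minus the start, and none equal that plus 1, so the table was read as counting from 0.

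The adjustment and the shuffle were tested on simulated data. Of 51141 simulated transcripts 200 were changed, with p-values from normal scores shifted by 2, 4 or 6. The shares called were 0% of 67 at a shift of 2, 67.2% of 67 at 4 and 100% of 66 at 6, and 7 unchanged transcripts were among the 118 calls. With none changed 0 were called. With calls in random order, 782 of 1000 shuffles gave as many pairs of higher units. Runs of 3 units planted at 30 places were all found, and 0 of 1000 shuffles gave as many pairs. The planting made this outcome near certain, so it checks the code only. Alternatives included other pseudocounts, a filter on level, no adjustment, the authors' own rule, 1 test per locus, centring of the ratios and an exchange of the groups. Leaving out samples, count-based fits, other normalizations and set tests need values per sample and were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.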

Results

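Leaf RNA was sequenced from barley of the cultivar Golden Promise in 2 groups of 2 samples. Plants of the transgenic group overexpressed HvHSFA6a, a gene of the heat stress transcription factor family, and the wild-type plants were not transformed. Per the labels' protocols the plants grew at 18 °C by day and 16 °C by night with 16 h of light, and the leaves came from plants of 3 weeks. The protocols also name a growth chamber at 34 °C to test heat tolerance, for wild type and transgenic plants alike. The labels give the transgenic samples a treatment of 42 °C for 30 minutes and call the wild-type samples controls, so that genotype and labelled treatment could not be separated. Protocols and labels thus differ in temperature, and whether the wild-type samples were heated is open. The deposited table gave 1 FPKM value per group, as a whole number, for 51141 transcripts of 17771 loci. These values summed to 949171 in the transgenic group and to 942627 in wild type. Values per sample were not used here, so that no difference below has a replicate check, and the depth is unknown. Directions below follow the group names in the table's column headers. The words for a rise or a fall in the authors' deposited table run the other way for all 1255 transcripts that carry one. With the groups exchanged, every direction below would turn.

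The comparison asked which transcripts differed between leaves of the HvHSFA6a overexpression plants and wild type. Among transcripts that passed the test, more were higher in the transgenic group than lower. Over all transcripts the tally leaned the other way, with 20610 higher and 23027 lower in the transgenic group whatever their p. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 2186 transcripts of 2052 loci passed a threshold of 0.05, of which 1380 were higher in the transgenic group and 806 were lower. The called transcripts that rose were thus 63.1% of all calls, with an exact binomial 95% interval from 61.1% to 65.2% that treats transcripts as independent. With the groups exchanged the share would be 36.9%. No locus held calls in both directions, with 1280 loci higher and 772 lower. Among calls above 0 in both groups, the median change was 4-fold for the 1111 higher transcripts and 3.33-fold for the 718 lower ones. A further 269 called transcripts were listed at 0 in wild type and 88 were listed at 0 in the transgenic group. Without adjustment, 5570 transcripts had a p under 0.05 in the authors' deposited table, against 2557 that a uniform spread of p-values would give, and their direction was nearly balanced, with 2973 higher and 2587 lower.

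The excess of higher transcripts grew with the size of the change. Of the 1321 calls with an absolute change from 1 up to 2 on the log2(FPKM + 1) scale, 59.0% were higher in the transgenic group (exact 95% interval 56.3% to 61.7%). Of the 96 calls with a change of 4 or more, 86 were higher and 10 lower, or 89.6% higher (81.7% to 94.9%). The excess was larger among transcripts of low level. In calls whose higher group lay from 5 up to 10 FPKM, 74.6% were higher in the transgenic group (69.3% to 79.4%), against 55.7% (51.3% to 60.0%) from 30 up to 100 FPKM and 60.6% (55.1% to 65.9%) from 100 up to 1000 FPKM. At 1000 FPKM or more the 21 calls divided into 10 higher and 11 lower. Called transcripts were spread over all 7 nuclear chromosomes, with shares called from 3.87% on 2H to 4.67% on 1H. The share of calls that were higher ranged from 60.2% on 6H to 67.5% on 5H, and the exact intervals of these chromosomes overlapped (53.6% to 66.5% and 62.3% to 72.4%).

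**Figure D1:**
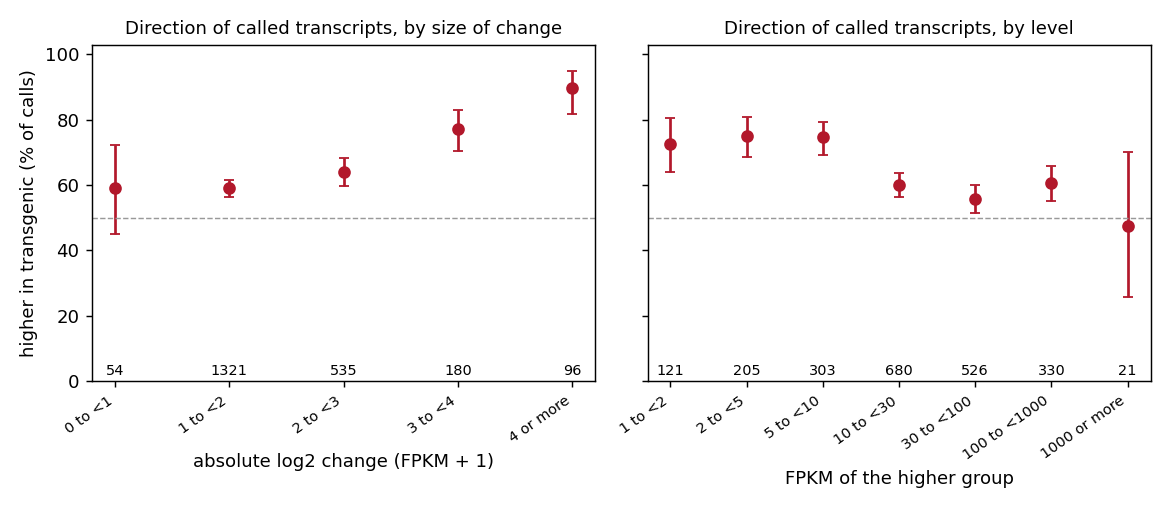
Share of called transcripts that were higher in the transgenic group (percent), by the absolute log2 change of FPKM + 1 (left) and by the FPKM of the higher group (right), with exact binomial 95% intervals, the number of calls above each axis and a dashed line at 50%. The share runs from 59.0% for changes from 1 up to 2 to 89.6% for changes of 4 or more.

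On the log2(FPKM + 1) scale, the gene model with the largest rise among calls above 0 in both groups was HORVU5Hr1G084230, on 5H from 571502302 to 571503774. Its called transcript had 1214 FPKM in the transgenic group and 2 FPKM in wild type, a 607-fold difference that rounding of the values bounds between 485-fold and 810-fold. HORVU7Hr1G049370, on 7H from 173201884 to 173205718, followed with 508 against 2 FPKM, 254-fold higher and between 203-fold and 339-fold with rounding. Summed over all transcripts of the locus, the values were 1327 and 2 FPKM for HORVU5Hr1G084230 (664-fold) and 1762 and 6 FPKM for HORVU7Hr1G049370 (294-fold). For both, the authors' deposited table gives a p of 5e-05, the smallest it holds, and the Benjamini-Hochberg adjusted value was 0.00221. Among calls above 0 in both groups, the largest falls on the same scale were in HORVU5Hr1G106120 and HORVU6Hr1G066450. The first lies on 5H from 623520556 to 623525019 and the second on 6H from 460085959 to 460095864. Called transcripts listed at 0 in 1 group are outside these rankings. HORVU5Hr1G106120 had 3 FPKM in the transgenic group and 152 in wild type, 50.7-fold lower (43.3-fold to 61-fold with rounding; adjusted p 0.00408 from the authors' p of 0.0001). HORVU6Hr1G066450 had 1 and 72 FPKM, 72-fold lower (47.7-fold to 145-fold; adjusted p 0.0275 from the authors' p of 0.001). Summed over the locus, the falls were 33-fold for HORVU5Hr1G106120 (7 and 231 FPKM), smaller than for its called transcript, and 104-fold for HORVU6Hr1G066450 (1 and 104 FPKM). The table pairs these gene models with no product name. No row of it carries the name HvHSFA6a, so the level of the overexpressed gene is not analysed here and the group labels were not checked by it.

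**Figure D2:**
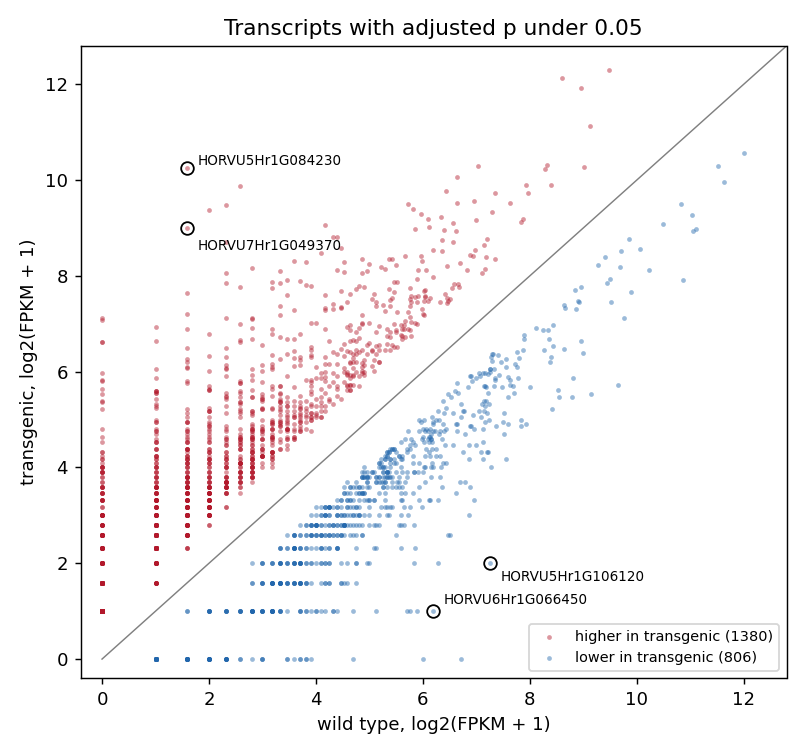
Called transcripts (Benjamini-Hochberg adjusted p under 0.05), each 1 point, with wild-type log2(FPKM + 1) on the horizontal and transgenic log2(FPKM + 1) on the vertical axis; the line marks equal values and circles mark the 4 named gene models. The 1380 transcripts above the line reach further from it than the 806 below.

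Gene lists were fixed before the data were examined as 33 patterns on product descriptions. Applied to the gene symbols of the table, 1 pattern matched, that of the photosystem and light-harvesting list, through 7 plastid transcripts. By their function rbcL and 4 plastid ribosomal protein transcripts belong to 2 other lists, and they are described with the plastid transcripts. The photosystem list showed no call, neither over all transcripts nor adjusted over the list alone, and none of its members had an unadjusted p under 0.05. In the transgenic group 4 members were higher and 3 lower. The list's median change was 0.53 on the log2(FPKM + 1) scale, at percentile 89.7 of 10000 random lists of the same size and matched mean level. psbA, which encodes the D1 protein of photosystem II, had 94 FPKM in the transgenic group and 65 in wild type. psbD, for the D2 protein, had 205 and 271 FPKM, and psbC, for an inner antenna protein, had 136 and 163. The transcript of psaI, a small subunit of photosystem I, was listed at 20 and 0 FPKM, with a p of 1 in the authors' deposited table.

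Plastid ribosomal RNA held the only call among 27 plastid transcripts, a share of 3.70% that is close to those of the nuclear chromosomes. The 23S rRNA was 2.82-fold higher in the transgenic group, at 946 FPKM against 336 in wild type. Its Benjamini-Hochberg adjusted p was 0.00582 (0.00015 in the authors' deposited table). The libraries were made with an mRNA kit, and how evenly ribosomal and transfer RNA were carried over in each sample is unknown. The 16S rRNA had 765 and 389 FPKM and did not pass, with an adjusted p of 0.148. Adjusted over the 5 plastid rRNA transcripts alone, a group formed after the values were seen, 2 passed, the 23S and the 16S rRNA. The main 5S rRNA transcript went the other way without passing, with 1798 FPKM in the transgenic group and 7378 in wild type, and the 4.5S rRNA had 630 and 559. Of the 20 plastid protein-coding transcripts 7 were higher and 12 lower in the transgenic group, and none passed. Their median change of -0.26 lay at percentile 16.3 of the random lists. The 3 with an unadjusted p under 0.05 were all lower in the transgenic group. They were rbcL, for the large subunit of Rubisco, with 123 against 190 FPKM, ndhK, for a subunit of the NDH complex, with 20 against 38, and rpl32, for a ribosomal protein, with 39 against 90. Of the 4 plastid ribosomal protein transcripts 1 was higher and 3 were lower. Some very short plastid transcripts had a value in a single group, while others, such as psbT with 257 and 126 FPKM, had values in both. trnL-UAA was listed at 0 in the transgenic group and 2152 FPKM in wild type, trnS-UGA at 615 and 0, and petN at 0 and 180, and none of these passed.

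**Figure D3:**
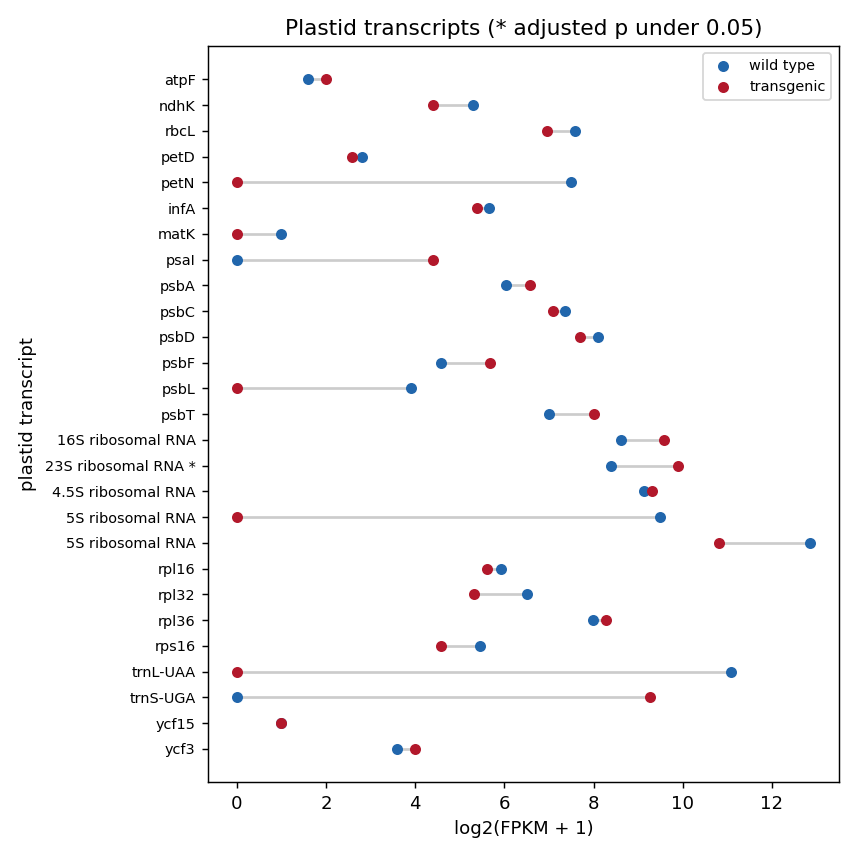
FPKM of the 27 plastid transcripts in the transgenic (red) and wild-type (blue) groups, on a log2(FPKM + 1) axis, with 1 row per transcript, the group's value as the point and an asterisk at the 1 transcript with an adjusted p under 0.05. Only the 23S ribosomal RNA is marked, at 946 against 336 FPKM.

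Nuclear non-coding RNA showed few calls, under the same limit of the mRNA kit. The groups are small, and the share called over all transcripts was low as well, from 3.87% on 2H to 4.67% on 1H. The few calls thus do not set these RNAs apart. Of 21 spliceosomal small nuclear RNA transcripts, 9 were higher and 12 lower in the transgenic group and 1 passed, a U1 RNA on 7H from 45851465 to 45851625 that was listed at 0 FPKM in the transgenic group and 11 in wild type (adjusted p 0.0329). None of 20 transcripts named as small nucleolar RNA and none of 17 named as nuclear large-subunit rRNA passed. These groups rest on names alone, and some rows are long, such as SNOR75 on 5H with 2371 nt. Some rows with a high value against 0 hold the largest p possible, such as snoZ279_R105_R108 on 5H at 0 and 113 FPKM. Whether the authors tested such rows is not given. Of 15 transcripts named as small-subunit rRNA, 1 on 5H with 2976 nt passed, at 1 FPKM in the transgenic group and 2 in wild type (adjusted p 0.0219). When adjusted over these 15 alone, a transcript on 2H from 751759723 to 751760258 passed as well. It went in the opposite direction, with 11 FPKM in the transgenic group and 3 in wild type. The 4 nuclear 5S rRNA transcripts, on unplaced sequence, held no call. Of these, 3 were listed at 0 FPKM in the transgenic group and 12 in wild type and 1 at 11 and 0. The median of -3.70 lay under all 10000 random lists, which were matched on mean level but not on length. The 3 also hold the same p in the authors' deposited table. However, petN, psbL and MIR169_2, which were likewise listed at 0 in the transgenic group, hold this p too. The equal p thus says nothing about a shared signal. Near-identical copies of this gene can share reads. The 3 may therefore still be 1 signal, and the place among random lists decides nothing. Of the 253 transcripts under 200 nt, 60.1% were listed at 0 in 1 group, against 36.4% of all transcripts, and 4 were called.

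Called loci were next to a called locus of the same direction more often than in shuffled order. With overlapping loci merged, 15811 units were placed on the 7 nuclear chromosomes, and 127 neighbouring pairs were both higher in the transgenic group and 70 both lower. When the calls were shuffled within chromosomes 10000 times, the mean numbers were 95.6 and 34.6, and 4 and 0 shuffles gave as many pairs. On 5H, 8 of 9 consecutive units from 493381379 to 493809187 rose, from 3.14-fold to 59-fold, with summed values of 1280 FPKM in the transgenic group and 119 in wild type. The unit without a call had 4 and 0 FPKM. On 6H, 5 consecutive units from 38404516 to 39696697 fell, from 3.29-fold to 5.33-fold, and summed to 800 and 2826 FPKM. On 1H, 3 units within 24.4 kb, from 548676518 to 548700924, fell from 3.87-fold to 4.60-fold. Another 3 units on 1H, from 385625811 to 385757976, rose from 2.0-fold to 17-fold. In all, 17 runs of at least 3 called units were found, 12 higher and 5 lower in the transgenic group, against a mean of 8.43 in the shuffles, 40 of which gave as many. The longest run without a break had 5 units, as on 6H. The mean longest run of the shuffles was 3.51 units, and 441 of the 10000 reached 5. Whether neighbours share reads through near-identical sequences was not tested.

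**Figure D4:**
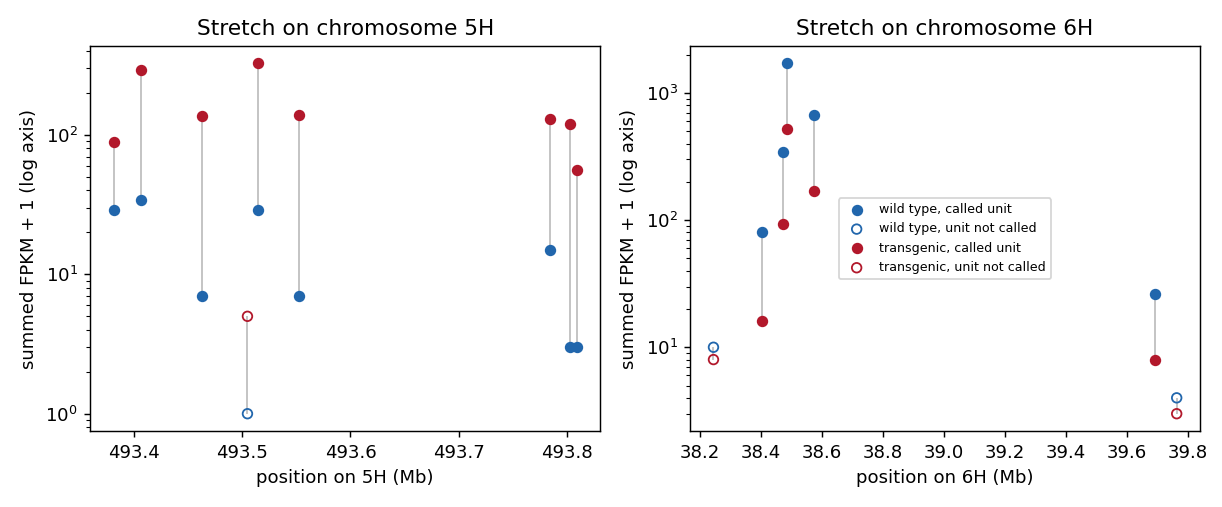
Summed FPKM + 1 (log axis) of each unit along a stretch of 5H (left) and of 6H (right), against the position in megabases, in wild type (blue) and the transgenic group (red), with filled points for units with a call and open points for units without. On 5H 8 of 9 units rose in the transgenic group, and on 6H 5 units fell, with 1 uncalled unit on either side.

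Some loci had signal in the transgenic group and were listed at 0 in wild type. Over all levels, 9446 transcripts were listed at 0 in wild type and 9192 at 0 in the transgenic group. At a summed 5 FPKM or more, 217 units were listed at 0 in wild type and 85 in the transgenic group. A call was held by 76 of the 217 and by 19 of the 85. Of the 217 units, called or not, 25 had a neighbour of the same kind. They made 14 neighbouring pairs, against a mean of 3.0 and a highest value of 13 in 10000 shuffles. The 85 units made 2 pairs against a mean of 0.436, a similar ratio (4.59 against 4.66) on a small count that 709 shuffles reached. On 7H from 84846525 to 85584772, all 19 transcripts of 4 loci were listed at 0 in wild type, with a sum of 211 FPKM in the transgenic group and 6 calls. On 1H from 553490631 to 553745135, 3 units were listed at 0 in wild type. The 2 that passed had 10 FPKM each in the transgenic group, and the third, with 315 FPKM, did not pass. The largest such locus, on 7H from 551084476 to 551088911, had 7 transcripts that summed to 1801 FPKM in the transgenic group and 0 in wild type. None of these 7 passed, and their smallest p in the authors' deposited table was 0.119. Of the 11 nuclear loci at 100 FPKM or more in the transgenic group and 0 in wild type, 7 had no transcript with an unadjusted p under 0.05 in the authors' deposited table.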

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

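Of the alternatives here, the pseudocounts of 0.1 and 5 were chosen before the data were examined and all others after. The count of 2186 called transcripts stayed within 1.5 times under 8 of 11 alternatives. Among these 8, exchanging the groups and centring the ratios could not change it, because calls rest on the authors' p alone. A 2-fold change at pseudocounts of 1 and 0.1 is the same filter on whole numbers (2132 each), and 1 test per locus counts loci. The count was 5570 without adjustment, where the threshold itself is looser, and 1255 under the authors' own rule of a 4-fold change above 0 in both groups. When a 2-fold change was asked for with a pseudocount of 5, which shrinks the change of low transcripts, it was 1413. The share of calls higher in the transgenic group was above 50% in the 10 alternatives that keep the column headers' direction, and 36.9% with the groups exchanged, which turns every direction by construction. It left the interval of the main value without adjustment (53.4%), with only transcripts at 5 FPKM or more in a group (57.8%) and with a 2-fold change at a pseudocount of 5 (60.9%). The cause was not tested. Centring the ratios on the median of the 7706 transcripts at 10 FPKM or more in both groups, which lay at -0.09, turned no call. So small a shift could hardly do so, since only 54 calls had an absolute log2(FPKM + 1) change under 1, and it decides little. For the 4 named gene models none of 12 alternative values that keep the headers changed direction, and 9 moved by 0.5 or more on the log2 scale. A pseudocount cannot change a direction, so only the sums over the locus could have done so. The photosystem list's median lay at percentiles 89.2 and 91.2 of random lists at pseudocounts of 0.1 and 5, and at 85.5 over the 5 members above 0 in both groups. With overlapping loci kept apart, 185 neighbouring pairs shared a direction, against 197. No paired analysis was possible because the table holds 1 value per group and no value per sample. For the same reason leaving out samples, the DESeq2 and edgeR fits that had been planned, other normalizations, unrounded counts and set tests were not run, and no filter on low values is the main setting itself. Rounding to whole FPKM widens the bounds of folds most for transcripts of low level.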

Other observations

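Wild type also had a stretch of its own. On 1H from 543886144 to 543943948, 3 neighbouring units summed to 39 FPKM in wild type and were listed at 0 in the transgenic group, and 1 of them passed. Among the 121 calls whose higher value was 1 FPKM, 88 were higher in the transgenic group and 33 lower. In the patterns below, the tests on pairs at least 50 kb apart and on pairs under 50 kb apart were fixed before their results were seen, and all other tests after.

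The direction words in the authors' deposited table run against its column headers. All 793 transcripts with the word for a fall were higher in the transgenic column, and all 462 with the word for a rise were lower. Headers exchanged after the words were given are argued against, since 0 of 18638 words for presence in a single group contradict the headers. Direction words written for wild type relative to transgenic stay open, since the 0 of 1255 words that disagree with that ratio only restate the pattern. Groups exchanged before the table was made cannot be told apart from this, because 0 names in the table match the overexpressed gene, and every direction given here rests on the headers.

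High values against 0 often came without a small p. Of 120 transcripts at 20 FPKM or more in the transgenic group and 0 in wild type, 96 had a p of 0.05 or more in the authors' deposited table, and of 39 opposite ones 33 did. Short transcripts as the whole cause are argued against, since 80.4% (exact 95% interval 71.4% to 87.6%) of the highest transcripts of 500 nt or more had such a p, counting 1 per locus. Reads shared between transcripts of 1 locus may contribute, as the share was 88.5% (79.9% to 94.3%) in loci with several transcripts and 33.3% (5 of 15, 11.8% to 61.6%) in loci with 1. Short length may contribute as well. In loci with 1 transcript, 11 of 21 found only in the transgenic group had such a p, against 5 of 13 at 500 nt or more. For those found only in wild type these were 5 of 8 and 0 of 2. Signal in 1 of the 2 libraries of a group stays open for all these transcripts, because 0 columns hold the value of a single library, and no biological explanation was tested.

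Neighbouring units called in the same direction numbered 197, 1.51 times the mean of the shuffles. Random order is argued against, since 0 of 10000 shuffles gave as many. Overlapping gene models that share reads are argued against as the whole cause, since overlapping loci were merged and 123 pairs lay at least 50 kb apart, against a mean of 91.7, with 5 shuffles as high. The excess was weaker for pairs higher in the transgenic group, 82 against a mean of 67.3 with 367 shuffles as high. For lower pairs it was 41 against 24.4, with 8 shuffles as high. Pairs under 50 kb apart were 1.92 times their mean, which may come from near-identical tandem copies that share reads or from copies regulated together, and these cannot be told apart without the sequences. The groups differ by genotype and labelled heat treatment, and neither these nor a difference between the plants' genomes over such stretches was tested.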
